A study of Mus musculus with 6 samples.

How the data were processed

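The series profiled CD8 T cells from the peritoneal cavity of 5 mice that carried MC38-LG tumours. MC38 is a mouse colon carcinoma line, and the LG form is not described in the sources used here. The mice had received antibodies against Tim-4, a phosphatidylserine receptor of cavity-resident macrophages, and against PD-1, an inhibitory receptor of T cells, on days 7 and 10 of the tumour challenge. The cells were sorted into subsets named PSlow and PShigh. The labels do not spell out PS, which is the usual abbreviation of phosphatidylserine, and the stain and gates of the sort are not given in the sources used here. The source label gives the peritoneal cavity, while another label calls the cells tumour-infiltrating. The 6 samples are an RNA, a hashtag and a T cell receptor (TCR) library for each subset, made with 10x 5′ chemistry from 10000 cells per library, per the labels. Each mouse carried its own hashtag, so the mouse was the replicate (n = 5) and a cell was not. Each subset was 1 library, so subset and library cannot be told apart in any comparison. The labels name several sequencers and a range of PCR cycles without saying which library had which.

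The deposited matrices hold whole-number UMI counts per gene and cell, written by Cell Ranger 4.0.0 per the file headers. The submitters' processing notes list Cell Ranger 3.1.0, STAR, Partek and Seurat 3.1 and the genome build mm10 without their roles. The authors also deposited estimated counts per gene and cell from Partek, which are not all whole numbers and cover only cells that passed a filter of the authors, whose limits are not given in the sources used here. These estimated counts served to define the filtered cells and, rounded to whole numbers, as an alternative count table. The TCR tables give UMI counts per assembled contig as deposited by the authors, and the hashtag tables give 1 mouse name per cell barcode. The tool that assigned hashtags is not given in the sources used here. Of the 31053 gene identifiers in the matrices, 31011 were found in the GENCODE vM21 annotation of mm10, which supplied coordinates and transcript lengths.

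The matrices held 9568 PSlow and 10153 PShigh barcodes with 500 or more UMIs. Of these, 2291 and 2452 had no mouse assigned, and the authors' filter removed 189 (1.98%) and 577 (5.68%), some of which had no mouse either. Cells with 1 mouse hashtag that passed the authors' filter were analysed, 7201 PSlow cells with a median of 3100 UMIs and 1293 genes, and 7340 PShigh cells with a median of 3490 UMIs and 1408 genes. Doublets were treated by the hashtag assignment and the authors' filter alone. An alternative also left out 595 cells with more than 1 productive TCR beta (TRB) chain or with UMIs above the 99th percentile. Raw counts were summed per mouse and subset, which gave 10 sums of 2860436 to 6031319 UMIs from 825 to 1703 cells.

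Genes were tested on these sums with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, filterByExpr) in R 4.3.3, with the mouse as a block, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The adjusted p-values of genes in all texts are from edgeR's quasi-likelihood test unless another tool is named, the error of a log2 difference is its standard error (SE), and CPM means counts-per-million values after TMM scaling. The design, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The block was to be used if hashtag names were the same in both subsets and TCR clones were shared more within a name than between names, and both held. As a second check of the pairing, deviations from the subset means correlated at 0.717 to 0.953 within a mouse and at 0.581 or less between mice, across genes. The rule for named genes took called genes with the same sign in 5 mice and a mean of 20 CPM or more in a subset, without TCR, immunoglobulin and mitochondrially encoded genes and without provisional names. From these it took the 12 largest increases and the 12 largest decreases, to which it added up to 3 called members with the smallest p of each list and 12 fixed markers. The results of 1 fixed marker and of some list members are not reported here, although they stay in the fits and the counts of calls. Genes named outside this rule were chosen after their values were seen.

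The 32 gene lists were tested, where 5 or more members were measured (26 lists), with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 in the blocked design. Camera with an estimated correlation and fry were run beside it. The lists include 9 of markers of other cells that a CD8 T cell gate could hold. Cells were clustered jointly with Scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes without 662 TCR and immunoglobulin genes (30 principal components, 20 neighbours, resolution 0.6). Clusters are given by number with their leading genes, and their sizes are not compared between subsets because genes that define them differ between the subsets. A shift in the make-up of cells, which can itself cause such differences, was therefore not measured. Subset contrasts within a cluster needed 20 or more cells in each sum, which cluster 2 met in 5 mice and clusters 1, 3, 5 and 8 in 4.

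A clone was a set of cells of 1 mouse with the same V gene, J gene and nucleotide CDR3 of the productive TRB chain with most UMIs. Clone-matched sums took, for each clone found in both subsets, the same number of cells from each. Expanded clones had 3 or more cells in a mouse over both subsets, and single-cell clones had 1. These gave 20 sums fitted together with a subset by class term. The mouse was the only block, so the pairing of the subsets within a mouse and class was not blocked. Differences between mice in how the classes differ thus stay in the error of this fit. Clonality was measured as the mean of 100 draws of 775 cells per mouse and subset, and tested with two-sided exact permutation tests over the 252 arrangements of 5 against 5 values, with sign flips within mice as the paired alternative, whose smallest p is 0.0625. Shares of cells with a UMI were computed after thinning each cell to 2012 UMIs and leaving out shallower cells, which were 73 to 187 cells per mouse in PSlow and 58 to 87 in PShigh.

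The fits were tested on simulated counts with 200 changed genes. Each sum was drawn independently around fitted means at the fitted dispersions, with the same contrast in every mouse. The rates that follow therefore need not hold for the real data. In the comparison of all cells, run on 9814 genes, 44.9% of genes changed 1.25-fold, 86.0% of those changed 1.5-fold and 100.0% of those changed 2-fold or 4-fold were called, as were 18 of 9619 unchanged genes. The recovery at 1.5-fold was 73.5% in the clone-matched comparison (9217 genes), 58.0% in the comparison within cluster 2 (6229 genes) and 32.7% for the difference between expanded and single-cell clones (8570 genes). Alternatives covered the block, DESeq2 1.42.0 size factors and Wald test, limma voom, filters on genes and cells, depth, clone definitions, clustering, and leaving out each mouse. Alternatives chosen after the data were seen were the Partek estimated counts, curves against transcript length and against GC content of the first 200 nt, leaving out cluster 12, contrasts in clusters 1, 3, 5 and 8 over 4 mice, lists without the authors' filter, lists without cells that held cycling markers with an estimated correlation, and the expansion difference without mouse 3. Statistics outside R used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures used matplotlib 3.10.9. The normalized and unfiltered Partek tables were not used here, because the UMI counts of the same cells were.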

Results

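CD8 T cells sorted as PSlow and PShigh from 5 tumour-bearing mice were profiled by single-cell RNA and TCR sequencing, with 7201 PSlow and 7340 PShigh cells assigned to a mouse. Median depth per mouse was 3135 ± 161 UMIs per cell in PSlow and 3526 ± 243 in PShigh (SD, n = 5). It was higher in PShigh in 5 of 5 mice (two-sided exact permutation test, p = 0.0159; paired sign flips, exact p = 0.0625, the smallest possible). A productive TRB chain was found in 89.2% of PSlow and 92.3% of PShigh cells. All mice had received both antibodies, so no comparison addresses the treatment itself.

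The first comparison asked which genes differ between PShigh and PSlow cells of the same mice. In PShigh cells 11 of 17 terminal exhaustion genes, 12 of 15 cytotoxic genes and 37 of 48 G2 and M phase genes rose, and 7 of 14 naive and central memory genes fell. No list call held with an estimated correlation (camera, lowest adjusted p = 0.284). Gzmb, which encodes the cytotoxic protease granzyme B, rose from 173 ± 105 CPM in PSlow to 408 ± 228 CPM in PShigh (SD, n = 5), a log2 difference of 1.26 ± 0.08 (SE, adjusted p = 2.58e-05, higher in 5 of 5 mice). Havcr2, which encodes the inhibitory receptor Tim-3, rose from 12 ± 8.50 to 35 ± 21.2 CPM (log2 1.5 ± 0.11, adjusted p = 2.94e-10). Klf2, a transcription factor that keeps T cells recirculating, fell from 703 to 449 CPM (log2 −0.79, adjusted p = 0.0340). Of 9910 genes tested, 1571 were higher and 1503 lower in PShigh.

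Among the other fixed markers, 3 further genes of chronically stimulated T cells were higher in PShigh in 5 of 5 mice. Pdcd1, which encodes PD-1, rose from 120 ± 77.7 to 204 ± 118 CPM (log2 0.78 ± 0.05, adjusted p = 2e-14), and Lag3, another inhibitory receptor, from 64.6 ± 33.4 to 114 ± 55.3 CPM (log2 0.83 ± 0.05, adjusted p = 1.47e-14). Entpd1, which encodes the ectonucleotidase CD39, rose by 0.66 ± 0.08 on the log2 scale. Mki67, a marker of dividing cells, rose from 22.1 ± 16.3 to 48.8 ± 28.4 CPM (log2 1.21 ± 0.14, adjusted p = 0.00013). Slamf6, a receptor of progenitor-type exhausted cells, fell by 0.38 ± 0.07, lower in 5 of 5 mice. Cx3cr1, a chemokine receptor of effector cells, fell by 0.70 ± 0.09 and was higher in 1 mouse, mouse 3. Il7r, the interleukin 7 receptor chain, fell by 0.36 ± 0.09 (adjusted p = 0.0421), a call that was lost on leaving out mouse 1, 2, 4 or 5 (adjusted p = 0.0838 to 0.117). The regulators Tcf7 (log2 −0.61 ± 0.16, adjusted p = 0.0563) and Tox (log2 0.16 ± 0.10, adjusted p = 0.247) did not pass. Mouse 3 had the smallest difference of Tcf7 (log2 −0.08), and without it Tcf7 passed (log2 −0.83, adjusted p = 8.17e-18).

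**Figure D1:**
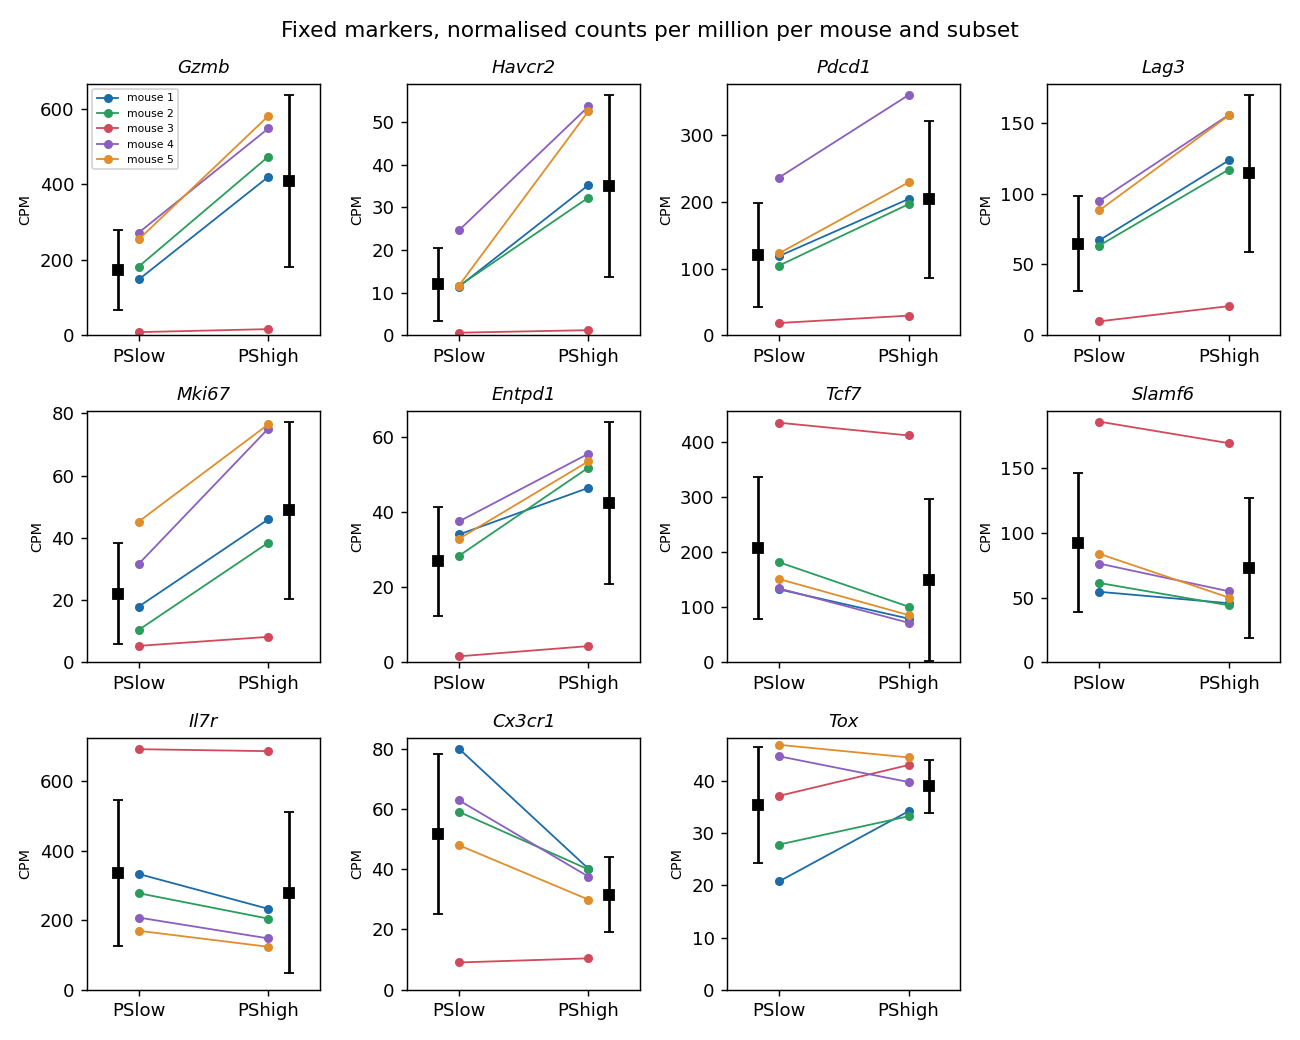
Expression of 11 fixed markers in CPM (vertical axes) for PSlow and PShigh cells of each of the 5 mice; lines join the sums of a mouse, and black squares with bars give the mean ± SD. The lines of Gzmb, Havcr2, Pdcd1, Lag3, Entpd1 and Mki67 rise in 5 of 5 mice, while mouse 3 is nearly level for Tcf7 (log2 −0.08) and Il7r (log2 −0.01).

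The largest increase was that of Gzmf, a granzyme of strongly activated mouse T cells (ENSMUSG00000015441, chromosome 14, 56205263 to 56211417 in mm10), from 8.44 ± 6.65 to 193 ± 161 CPM (log2 4.36 ± 0.45, adjusted p = 0.00294). Its neighbour Gzmc (chromosome 14, 56231441 to 56234656) rose by 3.09 ± 0.75 (adjusted p = 0.0439), a call that was lost on leaving out mouse 2, 3, 4 or 5 (adjusted p = 0.0807 to 0.134). The granzymes c to g are close paralogs that can share reads, so the split between Gzmf and Gzmc is uncertain. Lpcat4, a lysophospholipid acyltransferase (ENSMUSG00000027134, chromosome 2, 112239468 to 112247111), rose from 11.7 ± 2.56 to 59.4 ± 5.96 CPM (log2 2.32 ± 0.08, adjusted p = 3.77e-20). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose from 9.73 ± 5.57 to 29.7 ± 18.3 CPM (log2 1.62 ± 0.11), and Irgm1, an interferon-inducible GTPase, from 17.2 ± 2.86 to 49.1 ± 7.46 CPM (log2 1.51 ± 0.08). The other members of the 12 largest increases act in the cell cycle. They were the cyclin Ccna2 (log2 2.04 ± 0.41), the ubiquitin-conjugating enzyme Ube2c (1.86 ± 0.33) and the PCNA partner Pclaf (1.84 ± 0.34). Birc5 and Cdca8 of the chromosomal passenger complex (1.81 ± 0.37 and 1.62 ± 0.14) rose as well, as did the ribonucleotide reductase subunit Rrm2 (1.61 ± 0.12) and the histone gene Hist1h2ae (1.55 ± 0.19). Leaving out mouse 4 ended the calls of Ccna2, Ube2c, Pclaf and Birc5 (adjusted p = 0.0541 to 0.0850), leaving out mouse 1 those of Ube2c, Pclaf and Birc5 (0.0563 to 0.0855) and leaving out mouse 3 those of Ccna2 and Birc5 (0.0535 and 0.0616).

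The largest decrease was that of Adnp, a homeobox chromatin regulator (ENSMUSG00000051149, chromosome 2, 168180986 to 168207112), from 21.3 ± 2.55 to 1.3 ± 0.341 CPM (log2 −4.01 ± 0.17, adjusted p = 2.62e-18). Ankrd11, another chromatin regulator (ENSMUSG00000035569, chromosome 8, 122883822 to 123042277), fell from 291 ± 2.93 to 112 ± 4.71 CPM (log2 −1.38 ± 0.04, adjusted p = 2.04e-23). Pitpna, a phosphatidylinositol transfer protein, fell from 185 ± 16.3 to 64.8 ± 8.41 CPM (log2 −1.52 ± 0.05). The others included Ccnb1ip1, a ubiquitin ligase of meiotic crossing over (log2 −1.88 ± 0.12), the corepressor Rcor1 (−1.82 ± 0.10) and the intramembrane protease Sppl3 (−1.56 ± 0.10). They also included Ccdc71l (−1.49 ± 0.12), the MHC class II regulator Rfxap (−1.48 ± 0.08), Glcci1 (−1.46 ± 0.09), Ric1 (−1.45 ± 0.11), the depalmitoylase Abhd17a (−1.41 ± 0.06) and AY036118 (−1.35 ± 0.03). AY036118 (chromosome 17, 39847113 to 39848035) overlaps an annotated ribosomal RNA, so its reads cannot be assigned to it alone. All 12 were lower in 5 of 5 mice, which the rule for named genes required.

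**Figure D2:**
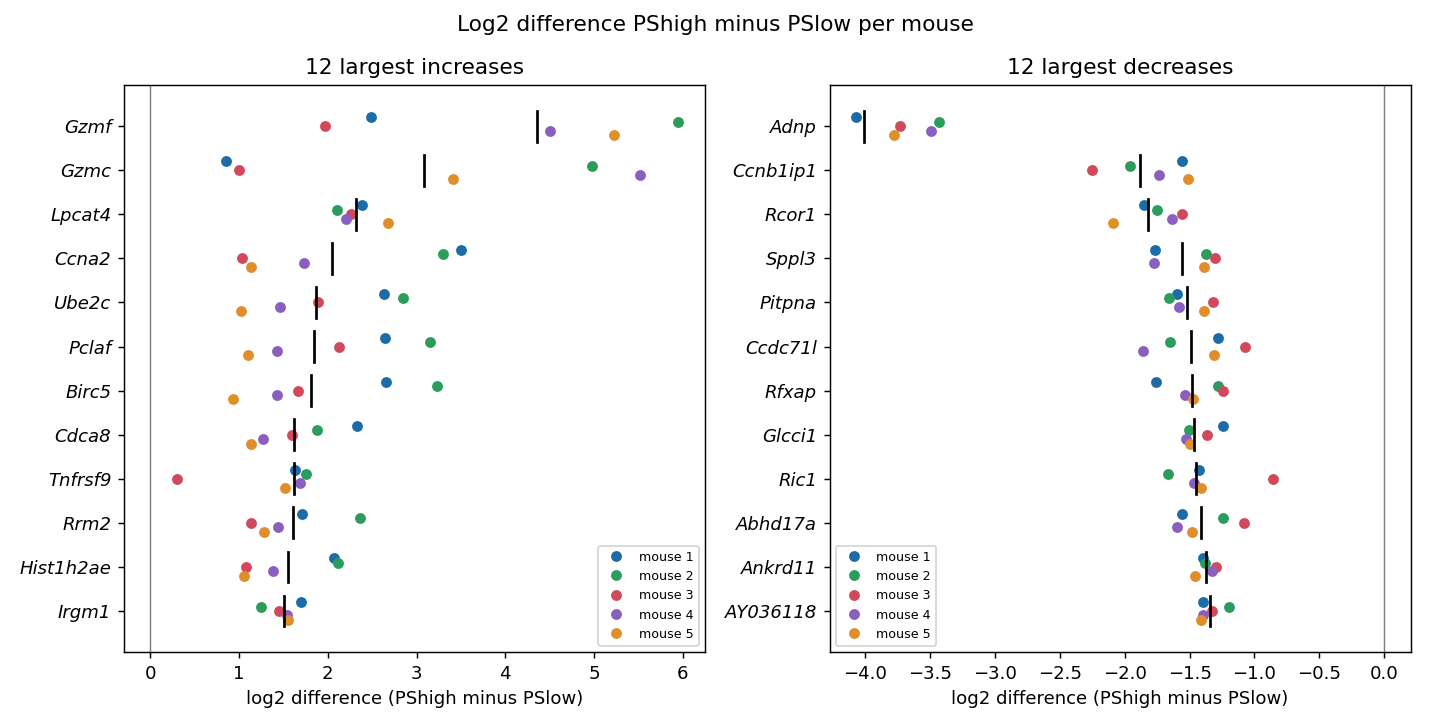
Log2 differences between PShigh and PSlow (horizontal axis) of the 12 largest increases and the 12 largest decreases; dots are the 5 mice and bars the fitted values. The dots of Adnp lie between −4.07 and −3.43, while those of Gzmf spread from 1.97 to 5.95.

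Genes of terminal exhaustion and of cytotoxicity moved mostly upward. In the terminal exhaustion list 11 of 17 measured genes rose, none fell and 6 did not pass, and the list was called higher (camera adjusted p = 2.74e-05; adjusted p = 0.284 with an estimated correlation). Beside Havcr2, Lag3, Pdcd1 and Entpd1 these included Rgs16, a regulator of G protein signalling (log2 1.37), and Tigit, an inhibitory receptor (log2 0.34). In the cytotoxic list 12 of 15 rose and 3 did not pass (camera adjusted p = 1.43e-05; adjusted p = 0.284 with an estimated correlation). Among them were the pore-forming protein gene Prf1 (log2 0.60), the protease gene Ctsw (0.29 ± 0.03) and the granule gene Nkg7 (0.20 ± 0.03). Gzma did not pass (log2 −0.34, adjusted p = 0.487). For both lists the counts adjusted over the list alone were the same. Of 10 costimulatory receptors 6 rose (camera adjusted p = 0.0107; adjusted p = 0.284 with an estimated correlation), including the interleukin 2 receptor chains Il2ra (0.73 ± 0.13) and Il2rb (0.23 ± 0.03), again 6 when adjusted over the list alone. Of 12 cytokines and chemokines 4 rose, namely Tnf (0.64 ± 0.09), Ifng (0.38 ± 0.07), Csf1 (0.60 ± 0.11) and Tnfsf9 (0.67), and 1, Tnfsf14, fell by 0.30 (camera adjusted p = 0.0453; adjusted p = 0.390 with an estimated correlation; the same counts adjusted over the list alone). The call of the cytokine list was lost on leaving out mouse 1, 2 or 3 (camera adjusted p = 0.0519, 0.0691 and 0.197). The chemokines Ccl3 (log2 1.43, adjusted p = 0.160) and Ccl4 (log2 1.0, adjusted p = 0.154) did not pass.

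Among genes of less differentiated T cells decreases outnumbered increases. In the naive and central memory list 7 of 14 fell, 1 rose and 6 did not pass (12 lower and 1 higher adjusted over the list alone), and the list was called lower (camera adjusted p = 6.14e-06; adjusted p = 0.375 with an estimated correlation). The genes that fell included the egress receptor S1pr1 (log2 −0.62), the transcription factor Lef1 (−0.56), Dapl1 (−0.57 ± 0.08) and the actin crosslinker Actn1 (−0.52 ± 0.05). Ly6c2, a surface protein also found on effector and memory cells, was the member that rose (0.27 ± 0.03). In the progenitor and stem-like memory list 6 of 14 fell and 8 did not pass (7 lower adjusted over the list alone; camera adjusted p = 0.000373; adjusted p = 0.380 with an estimated correlation). These included the transcription factors Foxp1 (−0.37 ± 0.06) and Bach2 (−0.58 ± 0.12). The effector differentiation list was split, with 3 of 11 genes higher, 3 lower and 5 not passing (the same adjusted over the list alone; camera adjusted p = 0.949). The lectin-like receptor genes Klrc1 (0.62 ± 0.06) and Klrd1 (0.49) rose, whereas the transcription factor Zeb2 (−0.64 ± 0.08), Cx3cr1 and the egress receptor S1pr5 (−1.84) fell.

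Most of the cell cycle genes rose. In the S phase list 32 of 35 genes rose, 1 fell and 2 did not pass (33 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.37e-13; adjusted p = 0.284 with an estimated correlation). Examples were Rrm2 and the thymidylate synthase gene Tyms (0.75 ± 0.08). In the G2 and M phase list 37 of 48 rose, 1 fell and 10 did not pass (40 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.6e-15; adjusted p = 0.284 with an estimated correlation). Examples were the topoisomerase Top2a (1.23 ± 0.08), the kinase Cdk1 (1.78 ± 0.13) and the spindle protein Tpx2 (1.65 ± 0.16), while Ctcf, a chromatin architecture protein, fell by 0.41. Without cells that held a UMI of Mki67, Top2a or Birc5, the median log2 difference of 63 members still measured was 0.17 against 0.55 in all cells, and 16 of them rose. Both lists were still called higher (camera adjusted p = 0.0110 and 0.0169; adjusted p = 0.281 for each with an estimated correlation).

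Genes of metabolism, the cytoskeleton and antigen presentation mostly rose. Of 15 glycolysis genes 9 rose (9 adjusted over the list alone; camera adjusted p = 0.000363; adjusted p = 0.375 with an estimated correlation), among them Pgam1 (0.45 ± 0.04), Gpi1 (0.26 ± 0.03) and Gapdh (0.31 ± 0.03), whose direction turned in the Partek estimated counts (log2 −0.19). Of 25 nuclear oxidative phosphorylation genes 18 rose (19 adjusted over the list alone; camera adjusted p = 4.97e-05; adjusted p = 0.317 with an estimated correlation), such as Cox5b (0.23 ± 0.03) and Sdhb (0.28 ± 0.04). In the cytoskeleton list 15 of 20 rose and 1, Crip1, fell by 0.08 (the same adjusted over the list alone; camera adjusted p = 6.48e-05; adjusted p = 0.380 with an estimated correlation), with Anxa2 (0.36 ± 0.03), Lgals1 (0.32 ± 0.03) and Tmsb4x (0.23 ± 0.02) among the increases. In the MHC class I list 11 of 13 rose (12 adjusted over the list alone; camera adjusted p = 2.86e-05; adjusted p = 0.338 with an estimated correlation). It was led by H2-T23, the mouse Qa-1 gene that presents to NKG2A receptors (chromosome 17, 36029773 to 36032855), from 83.5 ± 8.12 to 188 ± 33.6 CPM (1.16 ± 0.05), followed by H2-D1 (0.36 ± 0.02) and Psmb9 (0.35 ± 0.03). Of 13 mitochondrially encoded transcripts 9 fell and 1, mt-Atp6, rose by 0.11 (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00150; adjusted p = 0.380 with an estimated correlation), with mt-Nd6 at −0.74 ± 0.07 and mt-Atp8 at −0.37 ± 0.03.

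Several lists that camera did not call held members that moved both ways. Of 17 scramblase, flippase and related genes, which set phosphatidylserine exposure, 3 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.850). These were the scramblase family members Plscr1 (0.54 ± 0.07) and Plscr4 (0.69), the flippase subunit Tmem30a (0.23 ± 0.05) and the flippase Atp11b (−0.61 ± 0.10). The apoptotic scramblase Xkr8 did not pass (log2 0.19, adjusted p = 0.551). Of 16 apoptosis genes 3 rose and 2 fell (camera adjusted p = 0.424), including the effector Bak1 (0.24 ± 0.05) and the death receptor Fas (−0.34 ± 0.09). Of 10 anti-apoptotic genes 2 rose and 3 fell (camera adjusted p = 0.949), including Bcl2 (−0.27 ± 0.04) and Mcl1 (−0.18 ± 0.05). Both lists had the same counts adjusted over the list alone. Of 15 TCR signalling genes 7 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0505), with Cd3e at 0.27 ± 0.03 and the early activation marker Cd69 at −0.30 ± 0.05. The list was called higher on leaving out mouse 3 or 4 (camera adjusted p = 0.0440 and 0.0203). Of 18 type I interferon genes 1 rose, Isg20 (0.47 ± 0.05), and 2 fell, Ifit2 (−0.55 ± 0.15) and Ifit3 (−0.47 ± 0.14; camera adjusted p = 0.949). In the tissue residency list 3 rose, such as Rgs1 (0.68 ± 0.06), and 4 fell (12 measured; camera adjusted p = 0.949). Among 14 chemokine receptors and integrins 5 rose and 3 fell, such as the integrin Itga4 (−0.34 ± 0.05; camera adjusted p = 0.949). Calls were lost without mouse 1 for Mcl1 (adjusted p = 0.0574), without mouse 1 or 5 for Ifit2 (0.0563 and 0.0681) and without mouse 4 or 5 for Ifit3 (0.0784 and 0.190). The interferon, residency and chemokine receptor lists had the same counts adjusted over the list alone. Of 33 ribosomal protein genes 11 fell and 2 rose (the same adjusted over the list alone; camera adjusted p = 0.112), with Rps29 at −0.41 ± 0.03 and Rps28 at −0.36 ± 0.02. The list was called lower on leaving out mouse 1 (camera adjusted p = 0.0434). Of 15 dissociation and heat shock genes 4 fell and none rose (5 lower adjusted over the list alone; camera adjusted p = 0.218), among them Jund, an AP-1 subunit, from 606 ± 30.3 to 331 ± 22.5 CPM (−0.87 ± 0.03).

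Markers of other cells were sparse. In the list of CD4 and regulatory T cells 1 of 5 measured genes rose, Tnfrsf4, which activated CD8 T cells also express (1.55 ± 0.25; 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.121). In the natural killer list 1 of 5 rose, Fcer1g (0.90 ± 0.20; 1 adjusted over the list alone; camera adjusted p = 0.949; not called without mouse 1, 2 or 4, adjusted p = 0.0566 to 0.0766). In the B cell list 0 of 6 moved by edgeR (0 adjusted over the list alone; camera adjusted p = 0.777), Cd74 being nearest at log2 1.19 (adjusted p = 0.381). Shorter lists gave Cd68 for macrophages (0.52 ± 0.12; 1 of 2 measured genes, with 1 higher and 1 lower adjusted over the list alone). They also gave Trgv2 and Tcrg-C2 for γδ T cells (0.17 ± 0.05 and 0.28 ± 0.09; 2 of 2), and Cdh1 for tumour and stroma (0.56 ± 0.14; 1 of 2). Trgv2 was not called without mouse 2 or 4 (adjusted p = 0.0588 and 0.0544), nor Tcrg-C2 without mouse 1 or 4 (0.112 and 0.0598). For dendritic cells edgeR called 0 of 2, Itgax being nearest (log2 −0.18, adjusted p = 0.0789). The last 3 lists had the same counts adjusted over the list alone. The neutrophil and mast cell and the erythrocyte and platelet lists had 0 genes above the expression filter. Median, mean and camera direction differed in sign for the effector differentiation, chemokine receptor and natural killer lists (medians of −0.05, −0.04 and −0.04, direction up) and for the anti-apoptotic list (median −0.02, mean 0.16, direction down).

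Over 26 tested lists, camera called 10 higher and 3 lower, fry called 16 (12 up and 4 down), and camera with an estimated correlation called 0 (lowest adjusted p = 0.284; 2 lists at unadjusted p under 0.05). Under alternatives chosen after seeing the data, calls changed for 3 lists. Without the authors' filter the calls of the cytokine and costimulatory lists were lost (camera adjusted p = 0.178 and 0.0709). With a transcript length curve the cytokine list was not called (0.124) and the ribosomal list was called lower (4.39e-05). In a setting fixed beforehand, which left out cells with a UMI of Mki67, Top2a or Birc5, the TCR signalling list was called higher (camera adjusted p = 0.0292; adjusted p = 0.281 with an estimated correlation). Without the mouse block camera called 5 lists higher (S phase, G2 and M phase, glycolysis, oxidative phosphorylation and MHC class I) and 0 lower (2 at unadjusted p under 0.05), while edgeR called 66 genes higher and 280 lower. Of 102 named genes 78 then lost their call, among them Gzmb (adjusted p = 0.518), Pdcd1 (adjusted p = 0.611) and Havcr2 (adjusted p = 0.340). Those that kept it included Lpcat4, Gzmf, Irgm1, H2-T23, Jund and all 12 of the largest decreases. DESeq2 called 744 genes higher and 632 lower, edgeR after thinning called 953 higher, and edgeR on the Partek estimated counts called 2698 higher and 2719 lower. The log2 difference fell with transcript length (Spearman −0.380 across 5787 genes, which are not independent replicates; −0.227 to −0.338 within single mice).

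Contrasts within clusters asked whether the subsets differ among cells of like state. In cluster 2, led by Car2, Slamf6 and Tcf7, 188 genes were higher and 260 lower of 6393 tested in 5 mice. Without the block the counts were 27 and 127, and without mouse 3 the number of higher genes was 121. In 4 mice (mouse 3 had too few cells) cluster 1, led by Ly6g5b, Fgl2 and Csf1, gave 816 higher and 911 lower genes of 8716. Cluster 3, led by Gzma, Cx3cr1 and Zeb2, gave 122 and 233 of 6271, and cluster 5, led by Ccl3, Ccl4 and Tox, gave 54 and 165 of 6280. Cluster 8, led by Ifit1, Isg15 and Ifit3, gave 8 and 23 of 1934, among them Irgm1 (2.60) and H2-T23 (1.49). Of the genes also called over all cells, 1364 of 1380 moved the same way in cluster 1, 403 of 403 in cluster 2, 323 of 323 in cluster 3, 206 of 206 in cluster 5 and 31 of 31 in cluster 8, whose cells are part of the sums over all cells. Ankrd11 fell by about the same amount in clusters 1, 2, 3 and 5 (log2 −1.39, −1.25, −1.44 and −1.40), as did Jund (−0.92, −1.04, −0.95 and −1.0), and Lpcat4 (2.51, 2.30, 2.21 and 2.07) and H2-T23 (1.15, 1.2, 1.06 and 1.17) rose in each. Gzmb was called in clusters 1 and 3 (log2 1.17 ± 0.05 and 0.46 ± 0.08) and not in clusters 2 and 5 (0.17 ± 0.18 and 0.44 ± 0.15), although the test of the difference between clusters did not pass (adjusted p = 0.708). Klrc1 was called in clusters 1, 2, 3 and 8 (0.78, 0.40, 0.42 and 0.97). Pdcd1 was called in clusters 1 and 3 (0.72 and 0.37) and not in clusters 2 and 5 (0.21 and 0.22), and Lag3 in clusters 1 and 5 (0.66 and 0.54) and not in clusters 2 and 3 (0.07 and 0.10). Tcf7 was called in cluster 1 (−0.76) and not in clusters 2, 3 and 5 (−0.06, −0.15 and −0.31). Havcr2 (1.07) and Entpd1 (0.46) were called in cluster 1 and not in cluster 5 (0.65 and −0.16). Slamf6 (−0.40, 0.06, 0.13 and 0.01), Cx3cr1 (0.34, −0.65, −0.24 and 0.15) and Il7r (−0.05, −0.03, −0.11 and 0.10) were called in none of clusters 1, 2, 3 and 5 (adjusted p = 0.0984 to 0.996). The test of the difference between clusters passed for none of Pdcd1, Lag3, Havcr2, Entpd1, Slamf6, Cx3cr1 and Il7r (adjusted p = 0.192 to 0.990), and was not run for Tcf7. The mouse was the only block of that test, so differences between mice in how clusters differ stay in its error. A contrast that did not pass is thus not read as alike between clusters. The sums over all cells did not hold the make-up of clusters constant, so a difference there may reflect make-up, expression within a state, or both. Mki67 was not called in cluster 1 (log2 −0.15 ± 0.21, adjusted p = 0.684). The clusters were themselves formed on expression, which limits the contrast of genes that part them. All 6 cycling markers were raised in clusters 7 and 10, so the clustering had already set dividing cells apart from cluster 1. Slamf6 and Tcf7 lead cluster 2, and Cx3cr1 and Zeb2 lead cluster 3. A missing call of such a gene there is not read as equal expression in the subsets.

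Of 2706 genes called over all cells and tested across clusters 1, 2, 3 and 5, the contrast of 18 (0.665%) differed between clusters. They were Ccna2, the lectin-like receptor genes Klrd1 and Clec2i, Fxyd5, Ipo7, Tespa1, the translation-associated gene Tpt1 and 11 ribosomal protein genes. The other genes are not read as alike between clusters, since the pairing of the subsets within a mouse and cluster was not blocked.

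The next comparison held the TCR constant. For clones found in both subsets, equal numbers of cells were taken from each, 205 to 1063 cells per mouse and subset in 82 to 108 clones. Among these cells 6 of the fixed markers were higher in PShigh, and the gene lists were not tested there. Gzmb stood at log2 0.98 ± 0.04 (217 ± 130 to 425 ± 232 CPM, adjusted p = 1.56e-129), Havcr2 at 1.19 ± 0.11, Lag3 at 0.68 ± 0.06, Pdcd1 at 0.62 ± 0.05, Mki67 at 1.05 ± 0.09 and Entpd1 at 0.46 ± 0.09. Tcf7 (−0.61 ± 0.06), Cx3cr1 (−0.78 ± 0.08), Il7r (−0.39 ± 0.04) and Slamf6 (−0.36 ± 0.09) fell, and Tox did not pass (0.03 ± 0.10, adjusted p = 0.855). The SEs of Gzmb and Tcf7 were smaller than over all cells (0.08 and 0.16), although fewer cells of the same 5 mice were used. The very small p-values of this fit are therefore not read as a measure of the spread between mice. Of 9317 genes 1231 were higher and 1289 lower. The largest increases were Gzmf (4.03 ± 0.83, adjusted p = 0.0334), the kinetochore protein Cenpf (2.31 ± 0.18), Lpcat4 (2.21 ± 0.11), the mitophagy receptor Bnip3 (1.93 ± 0.17) and Ccna2 (1.86 ± 0.45). The largest decreases were Adnp (−4.03 ± 0.25), Rcor1 (−1.98 ± 0.14), Ccnb1ip1 (−1.94 ± 0.17), Sppl3 (−1.74 ± 0.13) and Rfxap (−1.65 ± 0.10). Without the mouse block 142 genes were higher and 375 lower.

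Cells of expanded and of single-cell clones were then compared between subsets. Among cells of expanded clones 797 genes were higher and 945 lower in PShigh, and among single-cell clones 205 and 269, of 8687 tested in both. Outside mouse 3 the sums held 606 to 1287 cells of expanded clones and 118 to 299 of single-cell clones. Mouse 3 held 225 PSlow and 268 PShigh cells of expanded clones, and 1194 and 891 of single-cell clones. The numbers of calls in the classes are therefore not compared with each other. Of the called genes, 352 were called in the same direction in both classes, and the log2 differences of genes at 20 CPM or more correlated at 0.750 across genes, which are not independent replicates. The contrast itself differed between the classes for 16 genes (626 at unadjusted p under 0.05). The stress-inducible gene Gadd45g rose among expanded clones (log2 0.84 ± 0.24) and fell among single-cell clones (−0.83 ± 0.22), a difference of 1.67 ± 0.33 (adjusted p = 0.0210). The activating receptor gene Klrk1, which encodes NKG2D, went the other way (−0.30 ± 0.08 and 0.50 ± 0.12; difference −0.81 ± 0.14, adjusted p = 0.0113), and Ahnak, a large scaffold protein, fell among expanded clones alone (−0.65 ± 0.05 against −0.07 ± 0.06; difference −0.58 ± 0.08, adjusted p = 0.00017). The tubulin gene Tubb4b (0.57 ± 0.12) and 11 ribosomal protein genes such as Rps20 (0.33 ± 0.06) had higher contrasts among expanded clones, and 1700025G04Rik a lower one (−0.94 ± 0.21). Without the mouse block the counts were 161 and 381 among expanded clones, 24 and 125 among single-cell clones, and 0 for the difference (242 at unadjusted p under 0.05). Without mouse 1, 2, 3, 4 or 5 the genes with a higher contrast among expanded clones numbered 2, 2, 24, 1 and 5, and those with a lower one numbered 9 without mouse 3 and 1 without mouse 1 or 4. Without mouse 3, Tubb4b (log2 0.44, adjusted p = 0.171), 1700025G04Rik (adjusted p = 0.0741) and Klrk1 (adjusted p = 0.0720) were not called. Among expanded clones the number of higher genes was 466, 493 and 531 without mouse 2, 4 or 5, and among single-cell clones it was 113, 83, 100 and 88 without mouse 1, 2, 4 or 5, with 177 lower genes without mouse 2.

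The TCR data asked whether clones were more expanded in PShigh. Most cells belonged to repeated clones in both subsets of 4 mice, and mouse 3 stood far below the others. At 775 cells per mouse and subset, 66.2 ± 29.5% of PSlow and 72.3 ± 28.6% of PShigh cells (SD, n = 5) lay in clones of 2 or more cells. The difference of 6.12 points was positive in 5 of 5 mice and smaller than the spread between mice (two-sided exact permutation test p = 0.468, adjusted over 3 measures p = 0.881; paired sign flips, exact p = 0.0625). The 10 largest clones held 44.2 ± 21.1% and 46.0 ± 19.9% of cells (exact p = 0.738, adjusted p = 0.881, higher in 4 of 5 mice; paired exact p = 0.5). This difference of 1.79 points was 3.86 without mouse 1, 0.823 without mouse 2 and 0.775 without mouse 4. The log2 effective number of clones (inverse Simpson) was 5.21 ± 2.11 and 5.14 ± 1.93 (difference −0.07, exact p = 0.881, adjusted p = 0.881, higher in PShigh in 1 of 5 mice). With paired sign flips its exact p was 0.812, and the difference turned positive without mouse 3 (0.00552) or mouse 4 (0.0210).

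**Figure D3:**
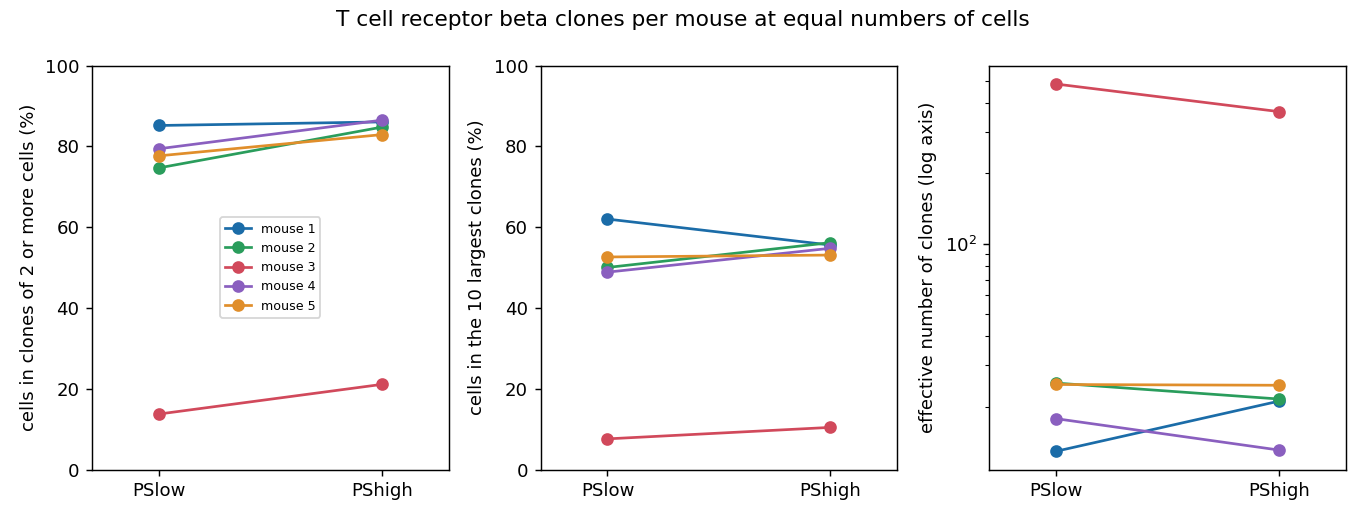
Share of cells in clones of 2 or more cells, share in the 10 largest clones (both in %) and effective number of clones (log axis) in PSlow and PShigh, each point a mouse at 775 drawn cells, with lines joining the subsets of a mouse. Mouse 3 lies at 13.8% and 21.1% of cells in repeated clones, while the other mice lie between 74.7% and 86.5%.

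Clones were shared between the subsets, least in mouse 3. The Morisita-Horn overlap of clone shares between PSlow and PShigh of the same mouse was 0.873 ± 0.164 (SD, n = 5), against 0.00307 on average and 0.0194 at most over the 20 pairs of different mice (exact permutation test over 120 pairings, p = 0.00833, the smallest possible; the same mouse was highest in 5 of 5). The permutation test addresses whether a hashtag name is the same mouse in both libraries, while the overlap values give the extent of sharing. Overlap was 0.929, 0.963, 0.582, 0.972 and 0.919 in mice 1 to 5. Of PSlow cells, 68.0 ± 29.2% belonged to clones also seen in PShigh, and of PShigh cells 73.5 ± 28.6% belonged to clones also seen in PSlow. In mouse 3 these shares were 16.3% and 22.6%, so most of its cells belonged to clones seen in 1 subset, while the other mice lay at 76.9% to 86.9% and 82.2% to 88.6%. Between different mice the shares averaged 2.24% and 2.35% and reached 9.14% and 11.9%. Of 4080 clones 465 had cells in both subsets and 3440 had a single cell, which lies in 1 subset by definition.

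Shares of cells with a UMI were compared at equal depth for the fixed markers. Gzmb was detected in 16.7 ± 9.30% of PSlow and 27.1 ± 13.8% of PShigh cells (SD, n = 5; 21% and 34% before thinning), Pdcd1 in 17.8 ± 9.82% and 26.4 ± 13.5%, Lag3 in 10.9 ± 5.59% and 17.7 ± 8.10%, and Havcr2 in 2.12 ± 1.53% and 5.58 ± 3.40%. Entpd1 was detected in 5.11 ± 2.79% and 7.91 ± 3.93% and Mki67 in 2.70 ± 1.45% and 4.53 ± 1.98%. These 6 shares were higher in PShigh in 5 of 5 mice but lay within the spread between mice (two-sided exact permutation tests, p = 0.0794 to 0.294, adjusted p = 0.503). Clusters 4 and 6, led by Dapl1 and Ccr7 and by Klra7, Fcer1g and Ikzf2, gave the background, with Gzmb in 1.03% of PSlow and 2.54% of PShigh cells, Pdcd1 in 1.03% and 1.27%, Lag3 in 0.738% and 0.635%, Havcr2 in 0.0738% and 0.106%, Entpd1 in 0.148% and 0.423% and Mki67 in 0.517% and 1.16% (median depth before thinning 3557 and 3541 UMIs, against 3228 and 3563 in all cells). Tcf7 was detected in 29.0 ± 13.2% of PSlow and 21.3 ± 16.2% of PShigh cells and Slamf6 in 14.6 ± 7.88% and 12.1 ± 8.07%, each lower in 5 of 5 mice (exact permutation tests, p = 0.429 and 0.468, adjusted p = 0.519). In cluster 1, which served as their background, Tcf7 was detected in 9.89% and 5.66%, itself higher in PSlow. Slamf6 was detected there in 2.32% and 2.38% (median depth before thinning 3192 and 3571 UMIs). Tcf7 was also called within cluster 1 (log2 −0.76), so its share there may hold expression. Free RNA was not measured apart from expression for these markers. Mouse 3 supplied 862 PSlow and 476 PShigh of the 1528 cells of cluster 4. It also supplied 343 and 333 of the 867 cells of cluster 6. The background from these clusters is therefore mainly that of 1 mouse. Cx3cr1 (8.94% and 5.75%, exact p = 0.222, adjusted p = 0.503, lower in 4 of 5 mice) and Il7r (38.0% and 34.2%, exact p = 0.667, adjusted p = 0.667, lower in 4 of 5 mice) did not pass either. Shares in the cells chosen as background were 0.221% and 0.212% for Cx3cr1 (clusters 4 and 6). For Il7r (cluster 1) they were 26.2% and 26.3%, which may be expression as well as background. Tox (6.09% and 6.85%, exact p = 0.476, adjusted p = 0.519, higher in 3 of 5 mice) was detected in 5.17% and 5.19% of cells of clusters 4 and 6. Pdcd1 had more transcripts over all cells (120 against 35.5 CPM in PSlow) but was detected there in 1.03% and 1.27%. The Tox share in these clusters is therefore not read as background. With sign flips within mice the smallest possible exact p of 0.0625 was reached by 9 of the 12 markers.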

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

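Both tests on mouse 3 were chosen only after its values were seen, and the tests on the cell cycle lists were chosen before. Mouse 3 stood apart from the other 4 mice in 22 of 138 groups of 5 values that were examined for a value far from the rest. Chance gives about 1 in 20 such groups, or 6.90, and many of the measures are related to each other. At 775 cells, repeated clones held 13.8% of its PSlow and 21.1% of its PShigh cells (74.7% to 85.2% and 82.9% to 86.5% in the others), and the 10 largest clones held 7.62% and 10.46% (48.9% to 62.0% and 53.1% to 56.2%). Its log2 effective number of clones was 8.92 and 8.52 (3.68 to 4.66 and 3.70 to 4.62), and its clone overlap between subsets was 0.582 (0.919 to 0.972). Tcf7 was detected in 52.0% of its PSlow and 50.0% of its PShigh cells (19.8% to 27.2% and 10.7% to 16.1%) and Slamf6 in 28.4% and 26.5% (8.99% to 13.6% and 7.56% to 9.32%). Entpd1 was detected in 0.268% and 1.03% (5.19% to 6.86% and 8.83% to 10.8%), and in PShigh Gzmb was detected in 3.41% (27.5% to 37.1%) and Lag3 in 3.73% (18.3% to 23.9%). Mitochondrial transcripts made up 2.71% of UMIs in PSlow and 2.65% in PShigh (2.20% to 2.22% and 1.99% to 2.07%).

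The log2 difference between PShigh and PSlow in mouse 3 lay apart for Tnfrsf9 (0.30, against 1.52 to 1.75), Tcf7 (−0.0789, against −0.90 to −0.73), Il7r (−0.0120, against −0.52 to −0.44), Pgam1 (0.33, against 0.47 to 0.50) and Gapdh (0.13, against 0.32 to 0.37). The labels give no difference in treatment for this mouse, so no biological explanation was tested. A hashtag that mixed several mice would share clones with them, but its highest overlap with another mouse was 0.00251. Fewer receptors would not leave a gap at equal numbers of cells, and the smaller of its gaps to the lowest other mouse was 60.9 points. Most of its 1637 PSlow and 1320 PShigh cells lay in clusters 4 and 6. There all 7 naive or central memory markers were higher than in other cells. Cluster 4 held 862 of its PSlow and 476 of its PShigh cells (12 to 59 and 8 to 25 in the others). Cluster 6 held 343 and 333 (14 to 43 and 9 to 40), and cluster 1 only 1 and 5. Its high Tcf7 and Slamf6 shares go with this make-up, whose origin was not tested. A mouse that differed before or during the experiment remains open.

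The subset contrast differed between expanded and single-cell clones by the interaction term for 16 genes. The difference was positive for Gadd45g (log2 1.67), Tubb4b (0.57), Rpl10 (0.34), Rps20 (0.33), Rps26 (0.32), Rpl36a (0.29), Rps6 (0.29), Rps2 (0.28), Rps12 (0.27), Rpl39 (0.27), Rpl35 (0.26), Rpl3 (0.24) and Rpl32 (0.23). It was negative for 1700025G04Rik (−0.94), Klrk1 (−0.81) and Ahnak (−0.58). Without mouse 3 the calls of Tubb4b (adjusted p = 0.171), 1700025G04Rik (0.0741) and Klrk1 (0.0720) were lost.

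Barcodes that the authors' filter removed enter none of the main comparisons, and of them only those with a mouse hashtag enter the alternative without that filter. A UMI of Mki67, Top2a or Birc5 was found in 98 of 189 removed PSlow barcodes (51.9%, exact 95% interval 44.5% to 59.2%) and in 471 of 577 removed PShigh barcodes (81.6%, 78.2% to 84.7%), against 9.01% and 16.5% of the cells analysed. The removed barcodes were deeper (medians of 9403 and 11067 UMIs against 3100 and 3490), which raises such shares, and no thinned share or background was computed for them, so no share of dividing cells is read from these values. The intervals cover counting error within 1 library per subset. The rise of S phase and G2 and M phase genes in PShigh was weighed against 3 technical explanations. The median log2 difference of both lists was 0.78, and it kept 146% of its size in cells taken without the authors' filter, 85.4% after thinning (68 members, median 0.52 against 0.61) and 105% without possible doublets (80 members). These values argue against the filter, depth or doublets as the whole source, and more dividing cells in PShigh may account for the rise, although subset and library coincide and free RNA was not tested for these lists.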

How the results depend on the processing

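Over all alternatives, 231 values of the main results kept their direction and side of the threshold or stayed within 1.5 times the reported count, 42 moved and 2 reversed. Of the values of named genes 1952 kept their call or stayed uncalled, 147 lost a call, 10 gained one and 3 reversed. Without the mouse block, which leaves the spread between mice in the error, 66 genes were higher and 280 lower over all cells, 142 and 375 in clone-matched cells, 161 and 381 in expanded and 24 and 125 in single-cell clones, 27 and 127 in cluster 2, 0 and 0 for the difference between clone classes (242 at unadjusted p under 0.05 by edgeR), and 5 and 0 lists by camera. Of all calls without the block 80.9% were lower, against 48.9% with it. With an estimated correlation camera called 0 and 0 lists (2 at unadjusted p under 0.05, while fry called 16). Over all cells DESeq2's Wald test gave 744 and 632, thinning 953 higher, and the Partek estimated counts 2698 and 2719 among 14443 genes, where Tox (−0.0459), Gapdh (−0.186) and Itgb2 (−0.0821) reversed. The difference between clone classes gave 4 and 1 genes with TRA and TRB together, and 56 and 27 without the expression filter (15745 genes tested). The cause was not tested, other than the wider sets of genes.

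Leaving out each mouse in turn gave 1154 to 1620 higher and 1087 to 1732 lower genes over all cells, 466 to 1057 and 642 to 1160 in expanded clones, 83 to 210 and 177 to 230 in single-cell clones, 1 to 24 and 1 to 9 for the difference between clone classes, and 121 to 194 and 201 to 238 in cluster 2. The difference in the log2 effective number of clones ranged from −0.27 to 0.02 (0.00552 without mouse 3, 0.0210 without mouse 4), that in the share of the 10 largest clones from 0.775 to 3.86 points, and the cause was not tested. Other scalings, filters and tools kept 60.3% (thinning) to 99% of the calls over all cells, apart from the block and DESeq2. The limits of depth were examined by thinning alone.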

Other observations

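The tests on transcript length, on the counting of reads and on the 12 largest decreases were chosen only after the results were seen. Receptors with the same V gene, J gene and amino acid CDR3 of the beta chain recurred between mice. Of 3945 distinct ones 15 were found in 3 or more mice. TRBV12-2 with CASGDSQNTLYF was found in 5 mice, with 5 nucleotide forms, in 74 PSlow and 81 PShigh cells. TRBV3 with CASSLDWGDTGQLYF was found in 5 mice, with 4 forms, in 25 and 18 cells. TRBV5 with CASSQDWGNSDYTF was found in 4 mice, with 3 forms, in 198 and 228 cells, and was among the 3 largest clones of mice 1 and 4. TRBV5 with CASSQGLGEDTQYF had 1 form in 3 mice (30 and 40 cells). Whether hashtags assigned to the wrong mouse add to forms shared between mice was not tested. The clone with most cells in mouse 1 (TRBV5, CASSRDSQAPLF) held 24.1% of PSlow and 15.7% of PShigh cells, and that of mouse 4 (TRBV12-2, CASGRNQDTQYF) 20.7% and 25.0%, whereas that of mouse 3 (TRBV3, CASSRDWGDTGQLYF) held 1.96% and 2.22%. The invariant NKT chain (TRAV11 with TRAJ18) was seen in 1 of 5504 PSlow and 0 of 6148 PShigh cells with a TRA chain.

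Gzmf transcripts lay mostly in PShigh cells, with a UMI at equal depth in 12 of 6482 PSlow cells (0.185%) and 255 of 6975 PShigh cells (3.66%). Cluster 11, which Gzmf, Gzmd and Gzmc themselves define, held 124 of these PShigh and 4 of these PSlow cells. Free RNA in the PShigh library would give unrelated cells a like share, but PShigh cells of clusters 4 and 6 had 20.9% of the share of cluster 1 (6 of 945 against 87 of 2863). This argues against free RNA as the whole source. PSlow cells of clusters 4 and 6 held a Gzmf UMI in 0 of 1355, so free RNA as a part of the source stays open. Most cells of clusters 4 and 6 came from mouse 3, which had only 1 PSlow and 5 PShigh cells in cluster 1. Clones missing from PSlow would not account for the Gzmf difference, since 94.1% of PShigh cells with a Gzmf UMI and a TRB chain belonged to clones with PSlow cells, whose PSlow cells held Gzmf in 11 of 2628 (0.419%). A candidate explanation is a state within shared clones that goes with PShigh, while reads shared between the granzyme paralogs and a difference between the libraries stay open.

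The difference over all cells was weighed against properties of the libraries, since each subset was 1 library. Removing a curve against transcript length kept 70.4% of the calls, and the authors' estimated counts kept 83.6%, which argues against a length trend or the counting as the whole source. A library factor that multiplies a gene alike in all its cells would give no more differences between clusters than other splits do, whereas 18 of 2706 called genes (0.665%) differed, which argues against it for these 18 alone. Of 11 tested members of the 12 largest increases 1 differed, Ccna2, and of the 12 largest decreases 0 by edgeR (2 at unadjusted p under 0.05), so a library factor and the subset cannot be told apart for decreases such as Adnp and Ankrd11, and the factor stays open for the other called genes, Lpcat4 and H2-T23 included. A like change in every state of PShigh cells may equally produce this.

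The counts of calls were set against other splits of the 10 sums, 100 drawn of 126 including the real one. For the 3074 genes over all cells 1 of 100 splits (the real one) gave as many, and the highest other gave 404. The real split was also alone for the 2520 genes in clone-matched cells (1 of 100, highest other 1196), the 1742 in expanded clones (1 of 100, 820), the 474 in single-cell clones (1 of 100, 110), the 16 of the difference between clone classes (1 of 100, 9) and the 448 in cluster 2 (1 of 100, 66). The split with 1196 genes exchanged only the sums of mouse 3 and parted all 5 pairs, as the real one does. Most of the 100 splits part fewer pairs than the real one, which leaves fewer mice to carry a contrast in the blocked fit. Only 16 drawn splits part all pairs, too few for a share under 0.05, so the splits cannot exclude chance for these counts. Among these 16 the highest other was 34 genes over all cells, 358 in expanded clones, 0 in single-cell clones, 0 for the difference between clone classes and 1 in cluster 2. For the 13 called lists the real split was not alone, as 19 of 100 splits gave as many and the highest other gave 17. For the 18 genes that differed between clusters, 1 of 32 splits gave as many and the highest other gave 1, while the 8 splits that part all pairs are again too few.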
